A study of Oryza sativa with 16 samples.

How the data were processed

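Binding of OsHOX24, a rice homeodomain-leucine zipper transcription factor of subfamily I, was mapped in seedlings of wild-type rice (WT) and of H49, a transgenic line that over-expresses OsHOX24, by sequencing the DNA pulled down with the protein (ChIP-seq). Seedlings 3 weeks old were either kept in water or desiccated for 3 h, per the series' design text. Chromatin was pulled down with an antibody against OsHOX24 on protein A beads and made into libraries with a commercial ChIP-seq kit, per the labels' protocols. The labels give 16 samples, of which 8 are ChIP libraries and 8 are inputs. Each of the 4 ChIP groups (WT control, H49 control, WT desiccation, H49 desiccation) has 2 replicates. The input samples were not analysed here.

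Reads were filtered with NGS QC Toolkit, mapped to the rice genome sequence MSU version 7 with Bowtie2 and passed to MACS2 for peak calling, per the series' design text. The MACS2 version was 2.1.1.20160309, per the submitters' processing notes; the Bowtie2 version is not given in the sources used here. The design text also names a Bedops step that selected confident peaks; whether that step entered the deposited lists is not given in the sources used here. Peaks were called separately for each ChIP library, as each of the 8 libraries has its own list. Whether the inputs served as background in peak calling is not given in the sources used here.

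Each deposited list holds 1 summit per line, as an interval of 1 bp with a peak name and a value, and no peak widths, read counts or fold enrichments. The value is the −log10 of the p-value that the authors' peak caller gave the summit; this unit was taken from the format MACS2 uses for summit lists, from a lowest value close to 3 in all 8 lists and from a tag in the deposited peak names read as a p threshold of 0.001. It grows with the number of reads and is not comparable between libraries. It was used to rank or filter summits within a list, to describe single regions and to order the named regions, an order that averages over libraries and so depends on which of them called a region. In 1 line the deposited peak name was damaged while its position and value were intact, and the line was kept. The number of reads behind each list is unknown, so no counting interval or detection limit could be given, and a summit missing from a list was treated as not called, not as unbound.

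The lists hold 29740 summits, of which 29684 lie on the 12 nuclear chromosomes and entered the comparisons. Positions are those of the deposited lists, counted from 1. Around each summit a window of 100 bp on each side was drawn, and windows of all 8 libraries that overlapped by at least 1 bp were merged into regions, so that summits up to 200 bp apart share a region. A region was called in a library where it held at least 1 of that library's summits. A confident region of a group was called in both of its replicates. A one-sided region was called in at least 3 of 4 libraries of one genotype or treatment and in 0 of 4 of the other. Windows stand in for peak widths, and neighbouring regions can hold summits of one broad peak.

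List lengths were compared on the log2 scale with exact two-sided permutation tests over the 70 assignments of 8 libraries to 4 against 4, whose smallest p is 0.0286. Within one treatment or genotype only 2 libraries face 2, the smallest two-sided p would be 0.333, and no test was made. Similarity of replicates was measured as the Jaccard index of called regions (shared regions over all regions called in either library) and tested one-sided over the 105 ways to pair 8 libraries. Numbers of one-sided regions were compared with those in all 35 splits of the 8 libraries into 4 and 4, using the larger side of each split. Overlaps of confident regions were set beside 1000 random placements over the chromosomes and beside 100 placements that shifted each region by up to 10 kb, which keeps the local density. Recurrence by strength was averaged over the 2 replicates of a group, which are scored on each other, and tested with an exact two-sided sign-flip permutation test over the 4 groups, whose smallest p is 0.125. Chromosome shares were tested with the same kind of exact test over the 8 libraries. P-values were adjusted by the Benjamini-Hochberg method within each family of tests. The labels do not say whether replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

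Bins of 100 kb that held on average at least 0.5% of a library's summits are called dense bins; this definition was made after the data were seen. Regions named in the text follow a rule fixed before the data were examined, moved from genes to regions because no gene positions were used: the 8 regions of each one-sided set, and the 8 among those called in all 8 libraries, with the highest mean −log10 p over the libraries that called them. Regions named outside this rule are said to be chosen after their values were seen.

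Planned tests of the subfamily's DNA motif at summits, of promoter positions and of 25 gene lists were left out, as was the naming of OsHOX24 itself, because they need a genome sequence and gene positions of the build the lists use. The gene table used for symbols belongs to another rice assembly, and none of its positions were used. Alternatives were the upper 50% of each list by −log10 p, equal numbers of the strongest summits (2172 per library), an overlap of 50 bp, all 4 of 4 libraries, removal of the regions called in all 8 libraries, the replicate number as a block, and each library left out in turn. Windows of 50 and 250 bp on each side, removal of the dense bins, removal of 2 libraries together, and permutation of the dense-bin share within replicate numbers were added after the data were seen.

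Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The region steps were tested on simulated lists for the comparison of H49 with WT, with 26483 regions: of 200 planted H49-only regions 197 were recovered, and of 200 planted regions in all 8 libraries 200 were recovered. In the same simulation 2 regions were called WT-only although none had been planted. The simulated background was scattered evenly along the chromosomes, and each planted site was given to every library of its set. These numbers therefore test the steps and are no error rates for the real lists, whose summits cluster and are often missed.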

Results

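The data were 8 lists of ChIP-seq summits for OsHOX24, from WT and H49 rice seedlings kept in water (control) or desiccated for 3 h, with 2 libraries per group. A summit is the position within a peak where the enrichment was highest. Both genotypes carry the endogenous OsHOX24 gene, so the WT libraries are not a background without antigen. The lists ranged from 2193 summits in WT desiccation replicate 2 to 9348 in WT control replicate 1. The median −log10 p of a list was between 6.10 and 7.81 in 7 libraries and 19.9 in WT desiccation replicate 2. Read depth is unknown.

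The summits were most frequent on chromosomes 1 and 3 and rarest on chromosome 11. Chromosome 1 held 17.8% ± 1.84 (SD, n = 8) of a library's summits while its length, taken as the highest summit position, was 11.6% of the 12 chromosomes. Chromosome 3 held 14.7% ± 2.21 of the summits against 9.77% of the length. Chromosome 11 held 2.58% ± 0.373 of the summits against 7.75% of the length, and lay below its length share in all 8 libraries. Each of these 3 differences had p = 0.00781 in an exact two-sided sign-flip permutation test, the smallest the 8 libraries allow, and 0.0134 after adjustment over 12 chromosomes. Chromosome 4, above its length share, and chromosomes 6, 7 and 8, below theirs, reached the same values in that test. Chromosomes 2, 5 and 9 passed as well, at adjusted p from 0.0208 to 0.0281 in the same exact test. Chromosome 10, at 6.38% ± 2.81 of the summits and 6.22% of the length, did not pass (p = 0.703 in the same exact test). Chromosome 12 did not pass either (p = 0.273 in the same exact test). The 8 libraries come from 4 groups and share regions, so these p-values measure how constant the shares were between libraries. Inputs were not compared, so a preference of binding for any chromosome was not tested.

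Merging the lists gave 16253 regions. Of these, 10505 (64.6%) were called in 1 library, 2641 in 2 libraries and 273 (1.68%) in all 8. Among the regions common to all 8 libraries the highest mean −log10 p was that of Chr3:5944471–5944732, at 244 ± 121 (SD, n = 8) and values from 79.5 in H49 control replicate 1 to 456 in WT desiccation replicate 2. It was followed by Chr9:21917061–21917291 (mean 203 ± 113), Chr2:21093462–21093712 (162 ± 101), Chr12:1793314–1793552 (161 ± 85.8) and Chr2:21656709–21656962 (149, from 70.9 to 299). The next were Chr6:28400635–28400856 (142 ± 87.0) and Chr6:28401345–28401596 (133 ± 92.4), which lie side by side, and then Chr2:24932660–24932909 (121 ± 79.7). Of the 273 regions, 49 lay on chromosome 1, 40 on chromosome 12 (14.7%, against 7.35% of the length) and 39 on chromosome 3. The dense bins described further on held 41 of the 273 regions (15.0%) and none of the 8 named here.

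The first comparison asked whether the number of binding sites differed between desiccated and control seedlings. The control lists were longer in both genotypes. WT control held 6262 ± 4364 summits (SD, n = 2) and WT desiccation 2442 ± 352, a ratio of geometric means of 2.24. H49 control held 3814 ± 601 and H49 desiccation 2352 ± 17.0, a ratio of 1.61. All 4 control lists were longer than all 4 desiccation lists (5038 ± 2910 against 2397 ± 210, n = 4 each), a log2 difference of −0.93. The exact two-sided permutation p was 0.0286, the smallest possible with 4 against 4, and 0.0857 after adjustment over the 3 measures compared per library, so the difference did not pass after adjustment. Without WT control replicate 1, whose list alone held 9348 summits, the ratio of control to desiccation was 1.49.

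**Figure D1:**
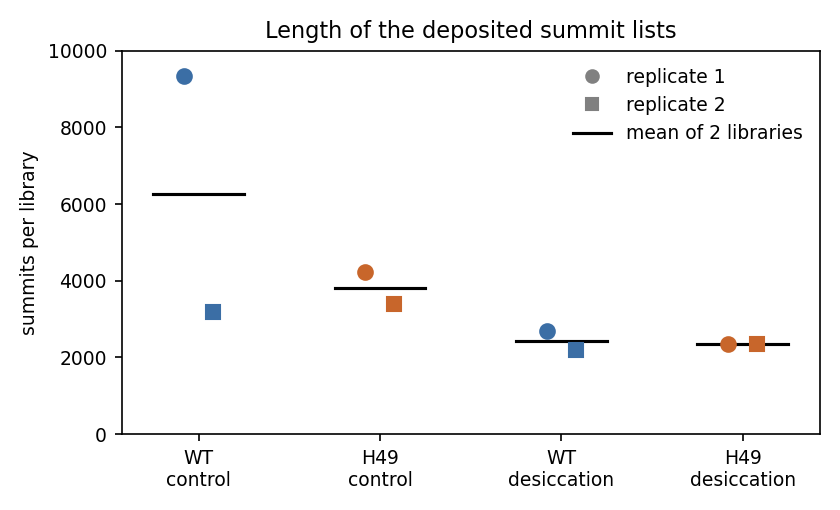
Number of summits in each of the 8 ChIP lists (vertical axis) by group, with WT in blue and H49 in orange, circles for replicate 1, squares for replicate 2 and a line at the mean of the group's 2 libraries. The control lists run from 3176 to 9348 summits and the desiccation lists from 2193 to 2691.

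Genotype made no comparable difference to list length. In control, WT lists held 9348 and 3176 summits and H49 lists 4239 and 3389, a ratio of H49 to WT of 0.696. In desiccation, WT lists held 2691 and 2193 summits and H49 lists 2340 and 2364, a ratio of 0.968. Over both treatments the log2 difference of H49 from WT was −0.29 (exact two-sided permutation p = 0.743, adjusted 0.886 over 3 measures, n = 4 each). Leaving out WT control replicate 1 turned its direction, to 0.17.

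The strongest summits of a library were the ones most often found again in the other library of its group. On average 57.5% ± 13.2 (SD, n = 4 groups, each the mean of its 2 libraries) of regions in the top 25% by −log10 p were also called in the other replicate, against 21.7% ± 3.54 in the bottom 25%. The shares in the parts between them, of 25% each, were 24.4% ± 4.74 and 28.4% ± 11.7. The top part exceeded the bottom part by 35.8 ± 9.87 percentage points and in 4 of 4 groups, with an exact two-sided sign-flip permutation p of 0.125, the smallest that 4 groups allow, so this design could not pass a threshold of 0.05. In WT desiccation replicate 2 the shares, from the weakest part to the strongest, were 29.5%, 26.1%, 8.87% and 33.8%. Where both replicates had a summit within 200 bp, the median distance between them was 51 bp in WT control, 44 bp in H49 control, 37 bp in WT desiccation and 35 bp in H49 desiccation.

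**Figure D2:**
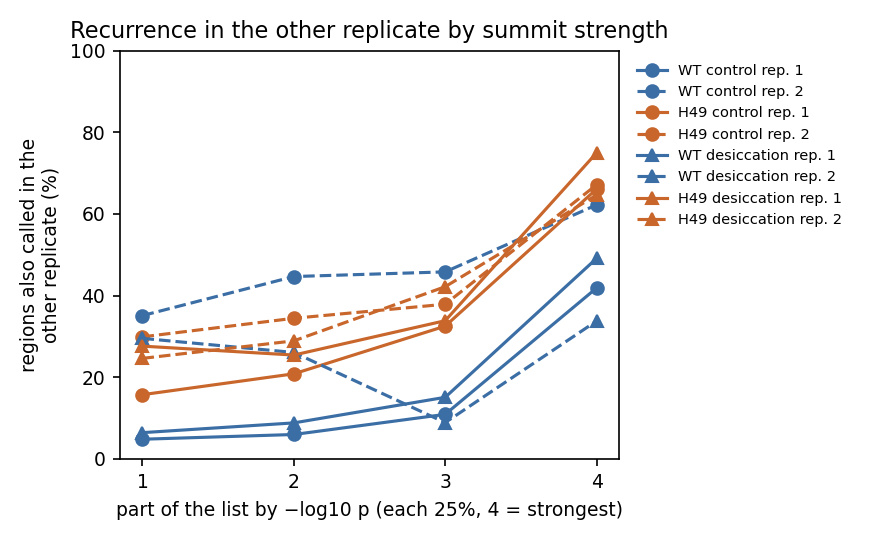
Share of each library's regions that were also called in the other replicate of its group (vertical axis, percent), for 4 equal parts of the library's own list in order of −log10 p (horizontal axis, 4 being the strongest). Each line is 1 of the 8 libraries, and the strongest part lies above the weakest in all 8.

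On average, replicates of a group were no more alike than libraries of different groups. The Jaccard index of the 2 replicates was 0.135 in WT control, 0.231 in H49 control, 0.123 in WT desiccation and 0.252 in H49 desiccation, a mean of 0.185 ± 0.0658 (SD, 4 pairs). The other 24 pairs averaged 0.189 ± 0.0559. The H49 pairs lay above that average and the WT pairs below it. The WT pairs hold WT control replicate 1, with the longest list, and WT desiccation replicate 2, with the highest median −log10 p. Among all ways to pair the 8 libraries, 57 gave a mean as high as the pairing of replicates (exact one-sided permutation p = 0.543, smallest possible 0.00952). The pair with the highest index was WT desiccation replicate 2 with H49 desiccation replicate 2, at 0.302, and the lowest was WT control replicate 1 with WT desiccation replicate 2, at 0.0761. In WT control replicate 1, 5434 of 9326 regions (58.3%) were called in no other library, against 17.0% to 30.5% in the other libraries.

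**Figure D3:**
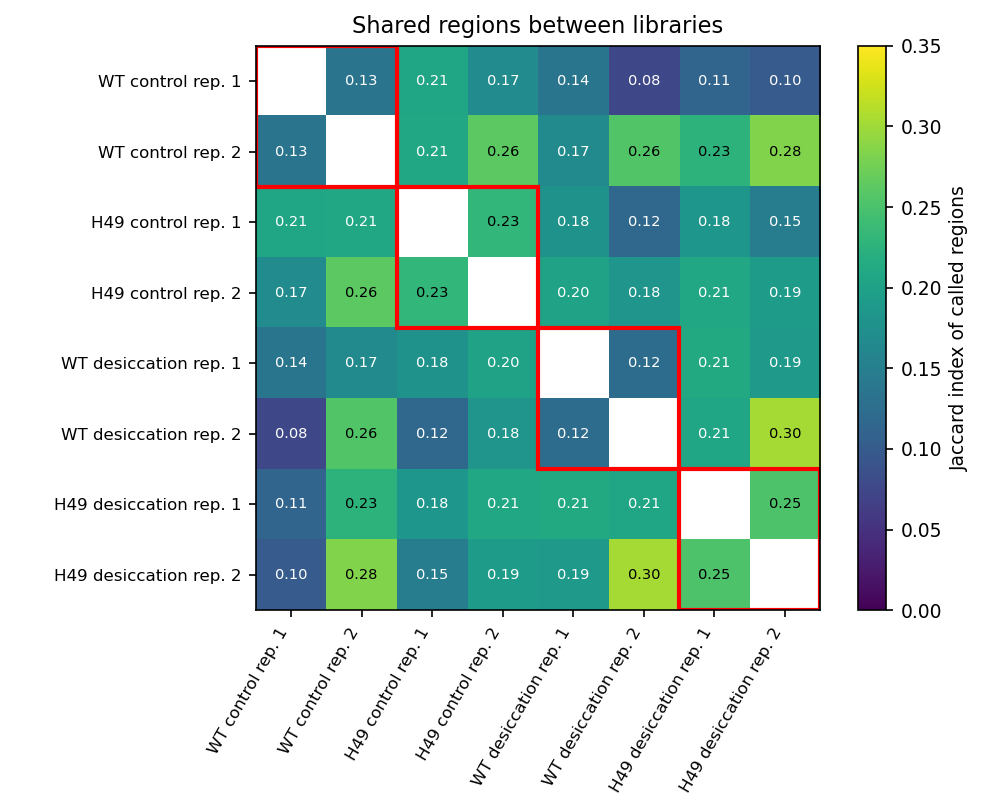
Jaccard index of called regions for each pair of the 8 libraries, as colour and number, with the replicate pairs of each group framed in red. The framed values run from 0.123 to 0.252, within the range of the unframed ones, 0.0761 to 0.302.

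Confident regions, called in both replicates of a group, numbered 1481 in WT control, 1427 in H49 control, 532 in WT desiccation and 943 in H49 desiccation. Random placements gave on average 49.2, 26.0, 9.69 and 9.89 overlaps, and placements shifted by up to 10 kb gave 350, 248, 85.6 and 185. Each observed number exceeded the highest of its random and shifted placements. A total of 2555 regions were confident in at least 1 group, and 1526 of them in exactly 1. H49 desiccation had the largest share of its confident regions in dense bins, 17.2%, and H49 control the smallest, 5.19%.

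The effect of over-expression was addressed by comparing H49 with WT within each treatment. In control, 785 regions were confident in both genotypes, 55.0% of the H49 regions and 53.0% of the WT regions (Jaccard index 0.370). A further 161 confident H49 control regions had no summit in either WT control library, and 259 confident WT control regions had none in either H49 control library. In desiccation, 343 regions were confident in both genotypes, 36.4% of the H49 regions and 64.5% of the WT regions (Jaccard index 0.303), with 164 regions in H49 alone and 71 in WT alone. Placements shifted by up to 10 kb shared on average 82.6 regions in control and 33.7 in desiccation. The other 2 ways to split the 4 libraries of a treatment gave 163 to 954 regions on a side in control and 103 to 406 in desiccation, so the numbers confined to one genotype did not exceed those of splits that ignore genotype.

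Over both treatments, 40 regions were called in at least 3 of 4 H49 libraries and in 0 of 4 WT libraries. Regions of one-sided sets are named in order of mean −log10 p over the libraries that called them; these values are not comparable between libraries, so the order depends on which libraries called a region and is no ranking of binding. The first was Chr1:36214129–36214369 (mean 38.2 ± 50.3, SD over 3 calling libraries), with 96.3 in H49 control replicate 2 but 10.1 and 8.21 in the others. It was followed by Chr4:8234559–8234779 (33.6 ± 25.4, with 62.9 in that library and 19.3 and 18.6 in the others), Chr2:15453164–15453462 (30.2 ± 23.3) and Chr9:1529958–1530173 (24.6 ± 16.9). The other members named by the rule were Chr12:13524307–13524522, Chr12:16855486–16855757, Chr8:18992969–18993227 and Chr12:12296819–12297086, at means from 13.8 to 21.2. All 8 were called in both H49 control libraries and in H49 desiccation replicate 1. With windows of 250 bp on each side, 1 of the 8, Chr9:1529958–1530173, no longer met the criterion. In the upper 50% of each list Chr12:12296819–12297086 did not meet it. In the whole set, 23 of 40 regions were missing from H49 desiccation replicate 2. Only Chr2:27888633–27889139 and Chr4:26361137–26361471 were called in all 4 H49 libraries, at mean −log10 p of 7.24 ± 2.77 and 4.88 ± 1.63; both were singled out after their values were seen.

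In the opposite direction, 38 regions were called in at least 3 of 4 WT libraries and in 0 of 4 H49 libraries. The highest means were those of Chr1:23311826–23312068 (mean −log10 p 20.1 ± 14.9, with 37.3 in WT desiccation replicate 2, whose list has the highest median, and 11.6 and 11.4 in the others), Chr7:27890224–27890520 (20.1 ± 18.7) and Chr3:6756318–6756585 (26.1 and 9.58 in control and 6.13 in WT desiccation replicate 2). Chr2:26143943–26144238 was called in all 4 WT libraries, at −log10 p of 15.3 and 15.5 in control and 10.4 and 11.5 in desiccation. Whether it or any other named region lies at the OsHOX24 gene, which H49 over-expresses, was not analysed here. Chr1:28523752–28524176 (11.9 ± 6.81) and Chr2:5931379–5931747 (10.8 ± 12.8) were also called in all 4. The remaining members named by the rule were Chr2:33953837–33954214 (12.6 ± 11.8) and Chr4:25843336–25843707 (10.7 ± 7.06). With windows of 250 bp on each side, 5 of the 8 named WT regions no longer met the criterion, Chr2:26143943–26144238 and Chr2:5931379–5931747 among them. In the upper 50% of each list 5 of the 8 did not meet the criterion. With equal numbers of the strongest summits 2 of the 8 did not. In the whole set, 24 of 38 regions were missing from WT desiccation replicate 2.

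Of the 35 splits of the 8 libraries, 34 gave at least as many regions on their larger side as the H49-only set of 40. The same number, 34, reached the WT-only set of 38, although this smaller side of its split was set against the larger side of the others. The highest other split, the one by treatment, gave 432 regions. The numbers of genotype-specific regions were therefore not above those of arbitrary groupings of the same libraries.

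The response to desiccation was addressed within each genotype. In WT, 386 regions were confident in both treatments, 72.6% of the desiccation regions and 26.1% of the control regions (Jaccard index 0.237). In H49 the number was 498, which was 52.8% of the desiccation regions and 34.9% of the control regions (0.266). Placements shifted by up to 10 kb shared on average 38.0 regions in WT and 57.0 in H49. H49 had 546 confident control regions with no summit in either H49 desiccation library, and 261 confident desiccation regions with none in either H49 control library. Both numbers were above all 4 sides of the other splits of the H49 libraries, 124 to 214, although 2 against 2 libraries cannot give a p below 0.333. In WT the numbers were 576 for control and 36 for desiccation, within or below the other sides, 122 to 683. Of the 261 H49 regions, 74 lay in dense bins; without them 187 remained, against 123 to 208 on the other sides.

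Several strong regions of one treatment within a genotype lay close together on chromosome 12; these regions and the 2 named beside them were chosen after their values were seen. Chr12:20485845–20486109 was called in both H49 desiccation libraries (−log10 p of 46.6 and 92.3) and in neither H49 control library. Chr12:20527280–20527557 was called in both H49 control libraries (22.3 and 62.7) and in neither H49 desiccation library. In WT, Chr12:20557627–20558126 was called in both control libraries (41.2 and 112) and in neither desiccation library. The neighbouring Chr12:20558384–20558633 was called in both WT desiccation libraries (17.2 and 83.8) and in neither WT control library. These neighbours lie so close that windows of 250 bp on each side would merge them into the same region, called under both treatments. The pair can therefore hold summits of a shared broad peak and does not show separate sites for each treatment. Strong regions lay elsewhere as well: the H49 control region with the highest mean was Chr9:4727067–4727368 (31.0 and 58.3), and the next in H49 desiccation after the one on chromosome 12 was Chr4:32891594–32891882 (39.1 and 82.5). Of the 546 H49 control regions, 432 (79.1%) had a summit in at least 1 library of the other genotype under the same treatment, against 88.7% of all confident H49 control regions. For the 261 H49 desiccation regions the number was 171 (65.5%, against 82.6%), for the 576 WT control regions 384 (66.7%, against 82.5%) and for the 36 WT desiccation regions 18 (against 86.7%).

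Over both genotypes, 432 regions were called in at least 3 of 4 control libraries and in 0 of 4 desiccation libraries, 83 of them in all 4. Only 30 were missing from WT control replicate 1, which has the longest list. WT control replicate 2 lacked 150, H49 control replicate 1 lacked 71 and H49 control replicate 2 lacked 98. The highest mean was that of Chr11:2391272–2391525 (mean −log10 p 42.0 ± 37.1, with 83.0 in WT control replicate 1), followed by Chr12:6762977–6763218 (40.3 ± 40.3, with 86.8 in H49 control replicate 2) and Chr4:21842197–21842434 (29.8 ± 28.9). The last was called in all 4 control libraries, as was Chr4:34981145–34981804 (23.1 ± 12.9). The other named members were Chr1:22605537–22605775 (27.2 ± 29.4), Chr10:19233140–19233434 (21.2 ± 12.2), Chr1:8084645–8084907 (20.8 ± 15.3) and Chr4:22402062–22402281 (19.6 ± 11.6). By chromosome, 78 of the 432 lay on chromosome 1, 81 on chromosome 2 and 78 on chromosome 3.

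Regions called in at least 3 of 4 desiccation libraries and in 0 of 4 control libraries numbered 68, of which 22 lay in dense bins. Of the 68, 33 were missing from WT desiccation replicate 1 and 26 from WT desiccation replicate 2. H49 desiccation replicate 1 lacked 3 and H49 desiccation replicate 2 lacked 2. The highest mean was that of Chr4:32891594–32891882 (mean −log10 p 45.8 ± 33.8), called in both H49 desiccation libraries and in WT desiccation replicate 1 and lying in a dense bin. The other 7 named members were all called in WT desiccation replicate 2, at 32.0 to 40.2 in a list with a median of 19.9, and not in WT desiccation replicate 1, so their place reflects which libraries called them. Outside the dense bins they were Chr9:14507931–14508151 (22.2, from 14.3 to 37.3), Chr5:12983833–12984049 (19.2 ± 16.8) and Chr7:12661747–12661973 (17.2 ± 17.3). The remaining 4 lay in dense bins on chromosomes 12 and 2, at Chr12:5611010–5611212, Chr12:5642464–5642723, Chr2:14285245–14285455 and Chr2:14251743–14252084. Those called in all 4 desiccation libraries were Chr8:23622639–23622928 (10.1 ± 3.29), Chr2:28989371–28989923 (8.10 ± 2.06), Chr5:6781897–6782176 (7.63 ± 1.03) and Chr3:31604065–31604448 (6.80 ± 3.38), singled out after their values were seen.

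The control-only set of 432 was the largest of the 35 splits, the next giving 367, which is a share of 0.0286. The desiccation-only set of 68 was reached by 28 of the 35 splits. It is the smaller side of its split and was set against the larger side of the others, so its low rank is partly built in. With equal numbers of the strongest summits per library (2172), the control-only set fell to 121 and the desiccation-only set rose to 109. At these lengths 6 of the 35 splits gave as many regions as the control-only set and 6 as many as the desiccation-only set, the highest other split giving 289, so the excess of control-only regions did not hold with lists of equal length. In the upper 50% of each list the control-only set held 217 regions and another split gave more, 224. With windows of 250 bp on each side, 3 of the 8 named control regions and 5 of the 8 named desiccation regions no longer met the criterion. In the upper 50% of each list 1 named control region and 2 named desiccation regions did not meet it. With equal numbers of the strongest summits 1 named desiccation region did not.

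**Figure D4:**
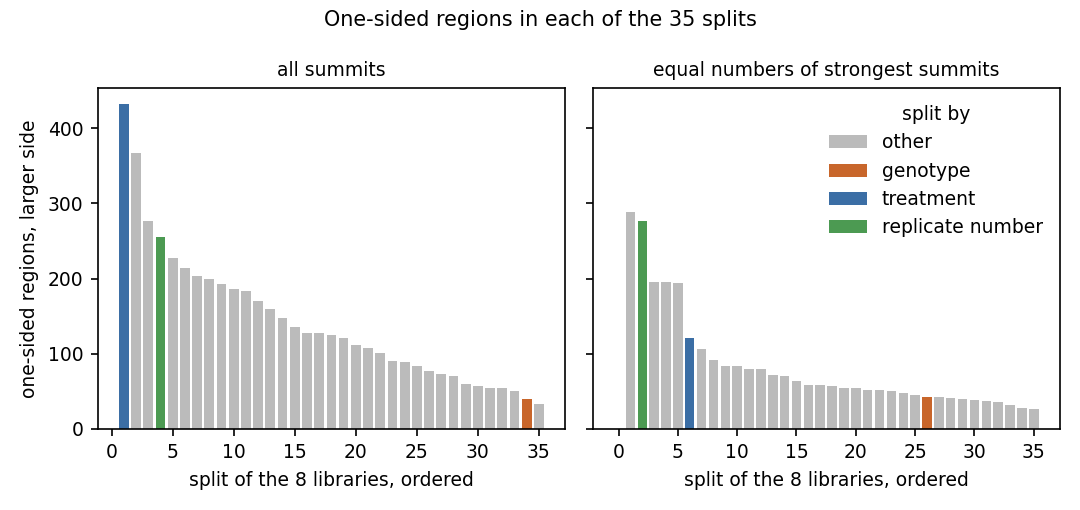
Number of one-sided regions on the larger side of each of the 35 splits of the 8 libraries into 4 and 4 (vertical axis), ordered from the most to the fewest, for all summits and for the 2172 strongest summits of each library. The split by treatment is the highest with all summits, at 432 regions, and the sixth with equal numbers, at 121; the split by genotype is near the low end with all summits, at 40.

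Summits were concentrated in 10 dense bins of 100 kb, and their number there differed greatly between libraries. The bin at Chr10:10800001–10900000 held 102 summits in WT desiccation replicate 2, 82 in H49 desiccation replicate 2 and 72 in WT control replicate 2, but 0 in H49 control replicate 1 and 0 in WT desiccation replicate 1. The bins at Chr4:9100001–9200000 (0 to 65 summits), Chr2:14200001–14300000 (0 to 54) and Chr12:5600001–5700000 (0 to 56) had the same 2 libraries at 0. In contrast, Chr4:32800001–32900000 held 14 to 20 summits in all 8 libraries, and Chr6:12500001–12600000 held 11 to 23. Dense bins took 1.18% of the summits in WT control replicate 1 and 21.5% in WT desiccation replicate 2. The share was 12.6% ± 8.32 (SD, n = 4) in desiccation and 4.75% ± 4.59 in control (exact two-sided permutation p = 0.200, adjusted 0.300 over 3 measures). It was 8.25% ± 6.47 in H49 and 9.12% ± 9.44 in WT (exact two-sided permutation p = 0.886, adjusted 0.886).

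**Figure D5:**
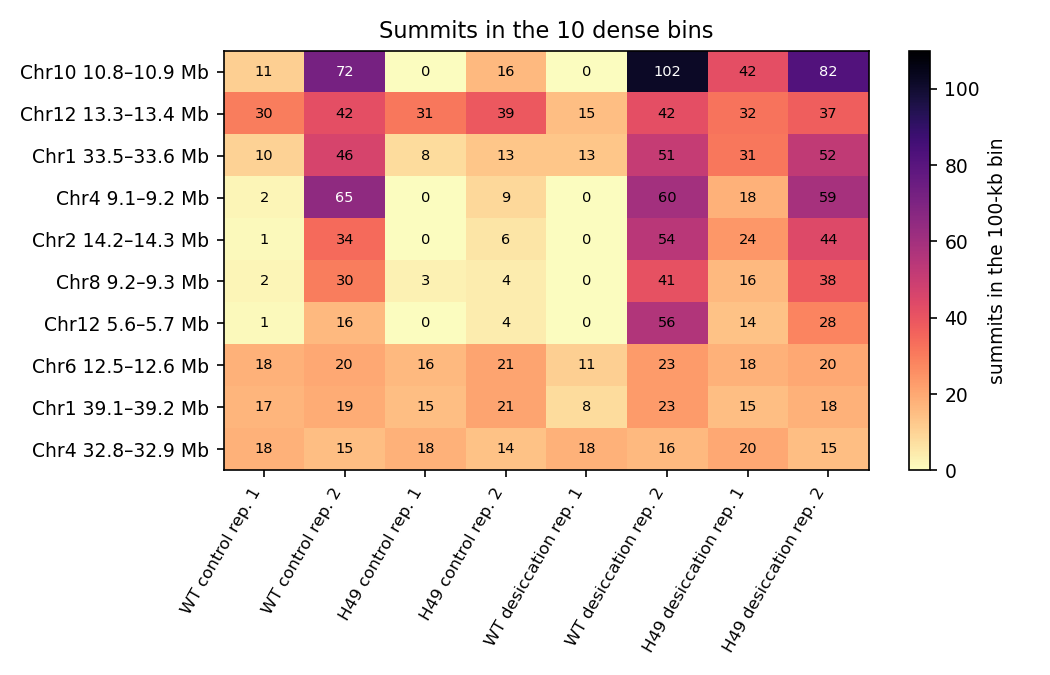
Summits of each library (columns) in the 10 dense bins of 100 kb (horizontal bands, with chromosome and position), as colour and number. The bin on chromosome 10 runs from 0 to 102 summits between libraries, while the lowest band, on chromosome 4, stays between 14 and 20.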

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

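The tests of WT control replicate 1 as the only cause, of treatment and genotype for the dense bins, of groupings by replicate number and of the dense-bin share within replicate numbers were chosen only after the result was seen, as were the check that the search for common positions can find repeated positions and the comparison of weak summits with the other genotype's control libraries. Leaving out each library in turn and counting one-sided regions over splits within replicate numbers had been planned, and the tests of weak summits, common positions and equal list lengths had their outcomes written down first, as had removal of the dense bins, an alternative added once the bins had been seen. Of 16 sets of 4 libraries tested for a library far from the rest, 3 had one, where chance gives about 1 in 20. The sets share libraries, and the median of WT desiccation replicate 2 was flagged in both its genotype set and its treatment set. The number of flags is therefore no measure of an excess over chance.

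WT control replicate 1 stood apart among the WT libraries with 9348 summits, against 2193 to 3176 in the others. The median −log10 p of 19.9 in WT desiccation replicate 2 stood apart both among the WT libraries and among the desiccation libraries, where the others lay between 6.10 and 7.72. Outside the 12 chromosomes used in the comparisons, the lists held 56 summits on the unplaced sequences, 34 on ChrUn and 22 on ChrSy, and 21 of the 56 came from WT desiccation replicate 2.

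The first pattern is that desiccation lists were shorter than control lists. It did not rest on WT control replicate 1 alone: without that library the log2 difference was −0.58, which is 62.6% of its size with it, and the remaining 3 control lists were still longer than all 4 desiccation lists. Confident control regions in the top 25% by −log10 p were called in a desiccation library in 97.8% of cases in both genotypes, while those in the bottom 25% were called in 31.5% in WT and 33.9% in H49, a ratio of at least 2.88. A ratio above 1 also arises with no change of treatment: in the other genotype's control libraries the same parts gave 99.2% and 60.9% for WT regions, a ratio of 1.63, and 97.2% and 79.8% for H49 regions, a ratio of 1.22. The ratios under desiccation met the outcome written down first for weak summits missed there. The ratios in control libraries were lower, but those lists were longer, so they are no matched reference. The ratio therefore does not decide whether weak summits were missed in desiccation. Fewer usable reads, weaker enrichment and lower occupancy of weaker sites stay open without read numbers.

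The split of regions by treatment bears on the same pattern. The 432 control-only regions exceeded all other splits, the highest of which gave 367. Only 1 of 35 splits, the real one, gave as many. That share, 0.0286, is under 0.05 but is the smallest that 35 splits allow, and it was not adjusted over the 4 one-sided sets. All 4 control lists were longer than all 4 desiccation lists, which can by itself enlarge the control-only set. The full lists therefore do not exclude chance or list length. In the upper 50% of each list chance is not excluded either, as 2 of 35 splits gave as many as the 217 regions (highest other 224). With equal numbers of summits it is not excluded, as 6 of 35 splits gave as many as the 121 regions (highest other 289). The 18 splits within replicate numbers, of which 1 gave as many as the 432 (highest other 214), are too few for a share under 0.05. For the 68 desiccation-only regions 28 of 35 splits gave as many (highest other 367), and with equal numbers of summits 6 of 35 gave as many as its 109 (highest other 289). For the 40 H49-only and the 38 WT-only regions 34 of 35 splits each gave as many (highest other 432), so chance cannot be excluded for these 3 sets. At equal numbers the split by replicate number, which is not a comparison of the study, gave 276 regions against 121 for treatment, and 2 of 35 splits gave as many as 276 (highest other 289), so chance is not excluded for it either. With the full lists the split by replicate number gave 255.

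The second pattern is the set of dense bins. Some of them fill in some libraries and are empty in others, while others, such as Chr4:32800001–32900000 with 14 to 20 summits, hold summits in all 8 libraries. The shares given here pool both kinds. A candidate explanation, copies of one sequence lying in several bins, was tested by searching for runs of summit positions repeated between bins at one offset. Of the dense bins, 0 of 10 shared such a run with another dense bin. With a tolerance of 20 bp the search found the positions of 8 of 10 bins again in the same bin of another library, and 10 of 10 with 50 bp. That check compared whole bins between single libraries, while the test used positions merged over all 8 libraries. Shorter or diverged copies were not tried, so the search does not exclude them. Neither treatment (exact two-sided permutation p = 0.200) nor genotype (exact two-sided permutation p = 0.886) can be told apart from other sources with 4 libraries a side, and the share also averaged 3.90% (1.18% to 9.85%) in the 4 libraries numbered 1 and 13.5% (4.35% to 21.5%) in those numbered 2 (exact two-sided permutation p = 0.0571). Treatment stays open in particular: the share was higher in desiccation in 4 of 4 pairs of the same genotype and number, and permuting only within the numbers gave an exact two-sided p of 0.0556, the smallest possible there, against 0.944 for genotype. The share also depends on list length, and the desiccation lists were shorter. Numbers of summits in dense bins fell from 110 in WT control replicate 1 to 65 in WT desiccation replicate 1. They rose in the other pairs, from 359 to 468 in WT replicate 2, 91 to 230 in H49 replicate 1 and 147 to 393 in H49 replicate 2. Different pieces of organelle DNA inserted in these bins may draw reads in libraries with more organelle DNA, which was not tested because it needs the genome sequence.

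The third pattern is that replicates were on average no more alike than other pairs. With equal numbers of summits the replicates' mean Jaccard index minus that of other pairs was −0.00886, short of the excess written down first. Without the dense bins the difference was 0.00123, short of it as well. Neither step alone made replicates more alike than other pairs on average. With full lists, leaving out 1 library at a time moved the difference between −0.0243 and 0.0283. A mean over 4 pairs therefore cannot exclude a part played by list length or dense bins. Grouping the libraries by replicate number gave a within-group excess of 0.0368 (exact one-sided permutation p = 0.0571) and by treatment 0.0346 (0.0857 in the same exact test), while genotype gave −0.0215; with equal numbers of summits number gave 0.0435 (0.0571) and treatment 0.0258 (0.114), and without dense bins number gave 0.0273 (0.0857) and treatment 0.0358 (0.0571), so which was higher depended on the summits used. Treatment and a shared processing day or sequencing run behind the replicate number both stay open, and the labels give no means to test the latter.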

How the results depend on the processing

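The windows of 50 and 250 bp, the removal of dense bins and the removal of both WT control replicate 1 and WT desiccation replicate 2 were chosen after seeing the data; the summed peak length could not be run because the lists hold no widths, nor the alternatives of motif, promoter and gene lists. The log2 difference of list lengths between desiccation and control lay between −1.10 and −0.58 with each library left out; leaving out any 1 desiccation library gave an exact p of 0.0857. It was −0.54 with both libraries removed (exact p = 0.100, the smallest possible with the libraries left, so this alternative could not pass). With the replicate number as a block it was −0.93 (exact p = 0.0556, the smallest possible in that design), which follows from fewer permutations; the labels do not tie the numbers together, and deviations from the group means of same-numbered libraries correlated at 0.0520 to 0.284 over 5475 regions, positive in each pair of groups but not above 0.1 in each, so the numbers were not taken as pairs. Under the block the genotype difference had an exact p of 0.722, and the one-sided sets of H49, WT, desiccation and control were reached by 17, 17, 13 and 1 of 18 splits, too few for a share under 0.05. The difference of H49 from WT lay between −0.53 and 0.17 with each library left out, reversed at 0.17 without WT control replicate 1, and was 0.0304 with both removed. Replicate similarity lay between −0.0243 and 0.0283 with each library left out. It reversed at 0.0283 without WT control replicate 2, 0.0138 without WT desiccation replicate 1 and 0.0179 without WT desiccation replicate 2. Without dense bins it reversed at 0.00123. No p passed, and replicate similarity was not computed with both libraries removed. One-sided sets in the order H49, WT, desiccation and control held 2, 3, 4 and 83 regions when all 4 of 4 libraries were required, 17, 17, 27 and 217 in the upper 50% of each list (another split gave 224), and 111, 2034, 341 and 754 with both libraries removed, where fewer libraries have to hold or lack a summit. With equal numbers of summits the WT set held 20, the desiccation set 109 and the control set 121. With each library left out they ranged from 45 to 227, 48 to 459, 75 to 246 and 472 to 1494. Regions confident in both groups numbered 460 (H49 and WT in control), 203 (H49 and WT in desiccation) and 204 (both treatments in WT) in the upper 50% of each list; 512, 70, 113 and, for both treatments in H49, 225 without the regions called in all 8 libraries; and 496 for H49 and WT in control with equal numbers. With each library left out they ranged from 883 to 1135, 390 to 591, 416 to 675 and 568 to 721. Except where construction shows it, the cause was not tested. Apart from the single named regions, which are not counted here, 97 alternatives kept the direction and side of the threshold or a count of similar size. Another 48 moved a count, 6 reversed and 6 lost the threshold. Unknown read depth limits every absence of a summit.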

Other observations

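The values in this part were chosen for description after the data were seen, and no hypothesis is offered.

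Outside the dense bins, single stretches of 100 kb stood out in some libraries. The first 100000 bp of chromosome 9 held 36 summits in WT control replicate 1, 33 in WT desiccation replicate 2, 22 in H49 control replicate 2 and 19 in WT control replicate 2, but 0 in H49 control replicate 1, 0 in WT desiccation replicate 1 and 1 in H49 desiccation replicate 1. In rice the end of the short arm of chromosome 9 carries ribosomal RNA genes. Chr12:20600001–20700000 was highest in WT desiccation replicate 1, with 36 summits, against 5 to 18 in the others. Chr6:23500001–23600000 followed the dense bin of chromosome 10, with 30 summits in WT desiccation replicate 2, 24 in H49 desiccation replicate 2 and 20 in WT control replicate 2, and 0 in H49 control replicate 1 and 0 in WT desiccation replicate 1. Chr3:6500001–6600000 went the other way, with 30 summits in WT control replicate 1 and 0 in WT desiccation replicate 2.

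Chromosome 12 held 8.29% ± 1.63 (SD, n = 4) of the summits in desiccation and 4.99% ± 1.17 in control. The exact two-sided permutation p was 0.0286, the smallest possible, and 0.229 after adjustment over 12 chromosomes, so the difference did not pass. Chromosome 11 held 2.84% ± 0.273 in H49 and 2.32% ± 0.276 in WT (exact two-sided permutation p = 0.0571, adjusted 0.686).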
